A study of Mus musculus with 12 samples.

How the data were processed

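Liver RNA was sequenced from 12 mice in 4 groups, combining genotype with diet. There were 4 libraries from double knockout mice on chow (DKO chow), 3 from double knockout mice on Western diet (DKO Western diet), 2 from double knockout mice with human APOA1 on chow (DKO/hA1 chow) and 3 from such mice on Western diet (DKO/hA1 Western diet). Groups and replicate numbers were taken from the labels, and every mouse had been on its diet for 22 weeks. Per the labels, RNA with an integrity number below 7 was discarded, and 8 to 9 libraries shared a lane of an Illumina Genome Analyzer IIx.

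The authors aligned reads with TopHat 1.3.2, Bowtie 0.12.8 and SAMtools 0.1.19 to mouse build mm10 and estimated expression with Cuffdiff, whose version and annotation the labels do not state. Although its name says counts, the deposited table holds FPKM, fragments scaled to transcript length and mapped fragments: values had decimals in every column and each library summed to between 379689 and 578927. The planned test on counts could therefore not be used, and limma on log2 FPKM replaced it. Its scaling, its level filter in FPKM, the value added before the log2 and the genes left out were settled after trial fits had been seen, which added 1 or 0.1, with and without median scaling, with a clock index, with replicate number, or without the 2 libraries highest in neutrophil markers. Read numbers per library are not used here, so no counting interval or floor is given. Relative depth was estimated from low values, in which 1 fragment is worth a step specific to the library. The steps placed the libraries between 0.514 and 1.31 of DKO chow replicate 1. The share of low values within 0.04 (log2) of a whole ratio of 4 or less was 60.8 to 67.5% in the other DKO chow libraries. It was 31.7 to 43.5% in the other groups, lowest in the deepest library, DKO/hA1 Western diet replicate 2. Depth is therefore less certain outside DKO chow, and why the share followed the group was not tested.

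The table listed 23284 genes. Of these, 5179 were at 0 in every library. Small RNA genes (778) were left out, a choice made after the table was seen. A further 21 genes were left out because they were listed at exactly 0 throughout at least 1 group while every library of another group had at least 1 FPKM, a rule chosen after seeing the data. They were Alb, Trf, Mup1, Mup2, Mup7 to Mup17, Mup19, Gm2083, LOC100048884, Raet1b, Rpl31-ps12 and S100g. Genes with an FPKM of at least 1 in at least 2 libraries were tested, 11546 in all, and 10939 fell below that level. Values were scaled by an unweighted trimmed mean of log ratios (trim 0.3 on ratios and 0.05 on levels), and 1 was added before the log2, which makes the fold changes of genes near or below 1 FPKM smaller than the ratio of their means.

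Tests used R 4.3.3 and limma 3.58.1 with a linear model of the 4 groups over all 12 libraries and a trended, robust moderated variance. A gene was called at a two-sided Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The planned comparisons were diet without APOA1, diet with human APOA1, genotype on each diet, and the diet by genotype interaction. Diet averaged over genotypes and genotype averaged over diets were added after seeing the data. Figures and the depth estimate used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

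The 35 gene lists were fixed before the data were examined. They covered cholesterol synthesis, fatty acid and triglyceride synthesis, lipid droplets and uptake, fatty acid oxidation, bile acids, lipoproteins and sterol efflux, cytokines and chemokines, acute phase, interferon response, MHC class II, extracellular matrix, unfolded protein response, oxidative stress and glutathione, drug metabolism, gluconeogenesis, clock and cell cycle. Marker lists covered hepatocytes, macrophages and Kupffer cells, lipid-associated macrophages, T and NK cells, B cells, neutrophils, endothelium, stellate cells, cholangiocytes, red blood cells, pancreas, adipose tissue, skeletal muscle, immediate early genes, mitochondrially encoded genes, male-biased and female-biased liver genes, and Y chromosome genes with Xist. Lists with under 3 tested genes were not tested (pancreas 1, adipose tissue 1, skeletal muscle 0, mitochondrially encoded 0). Lists were tested in limma with camera on the log2 FPKM (planned on log2 counts) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, under which no list was called in any comparison. In addition, list means per library were compared by exact permutation of the libraries, within genotype or within diet for the averaged comparisons. For each list called by camera, the median, the mean and the test had the same sign. Lists for intestine, neutrophil precursors and parts of the clock were added after seeing the data.

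The named genes followed a rule fixed before the data were examined. It took Apoa1 and Apoe, then the 8 largest rises and 8 largest falls per comparison among called genes with a mean FPKM of at least 1 and no overlap between the groups, leaving out predicted genes, and then up to 4 called members of each list with the smallest p. The level condition was first written for counts and was changed to FPKM. The condition on overlap did not apply to the interaction, as planned. In both averaged comparisons, which came later, it was applied between the diets within each genotype. The largest changes named for genotype averaged over diets were therefore chosen partly on their diet values. Where no gene was called, the 3 positive and 3 negative genes with the smallest p are given as values. A gene that the rule named is not reported. Positions are from RefSeq on GRCm38.p6, to which mm10 corresponds. Single values were compared by two-sided exact permutation tests.

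The test was also tried on simulated data: 200 genes were changed in libraries drawn gene by gene, without dependence between genes, from normal noise around its mean with its moderated SD, and scale shifts between libraries were put in. Real genes move together, so the recovery shown is for independent genes. The simulated sets gave 96 to 160 called genes in the comparisons that follow, which loosens the adjusted threshold. The recovery does not carry over to real comparisons with few called genes. Among the 2-fold changes it recovered 83.6% for diet without APOA1, 71.6% for diet with human APOA1, 70.1% for genotype on Western diet, 67.2% for genotype on chow and 40.3% for the interaction. Among the 1.5-fold changes the recoveries were 47.8%, 11.9%, 23.9%, 23.9% and 8.96%.

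The alternatives set beforehand were median-ratio scaling, equal totals, no level filter, a stricter filter of 3 libraries, a replicate block, the first number of the sample code as a random block, a fold threshold of 1.2, only the libraries of the 2 groups compared, and leaving out each library in turn. Alternatives added after seeing the data were a pseudocount of 0.1, values as deposited, a clock index as covariate, array weights, and fits without the 2 libraries highest in neutrophil markers, without the 2 highest in intestine markers, or without Mup and ribosomal protein genes. The labels state no pairing of mice. First code numbers were 41, 43, 44, 47 and 49 on Western diet and 54, 56, 57 and 59 on chow. None was shared between diets, so diet and any batch that followed these numbers cannot be told apart. Number 57 was shared by both DKO/hA1 chow libraries and 1 DKO chow library, and number 41 by 1 library of each genotype on Western diet, too few for values within a number.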

Results

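Liver transcripts were measured by RNA sequencing in mice labelled as double knockouts of apolipoprotein A-I and apolipoprotein E (DKO), and in mice with the same double knockout that carried a human APOA1 transgene (DKO/hA1). Apolipoprotein A-I is the main protein of high-density lipoprotein, and apolipoprotein E directs the uptake of lipoprotein remnants by the liver. Mice of each genotype ate standard chow or a high-fat Western diet for 22 weeks. There were 4 DKO chow, 3 DKO Western diet, 2 DKO/hA1 chow and 3 DKO/hA1 Western diet libraries. These n apply to all group values, in which ± is the SD. After a log2 fold change, ± is the SE. FPKM summed to 379689 to 578927 per library, and 10252 to 10963 genes per library reached 1 FPKM. Without the 21 genes left out for zeros throughout a group, the 10 most abundant genes held 12.3 to 27.9% of the remaining total. The highest shares were in DKO Western diet replicate 2 (27.9%) and DKO/hA1 Western diet replicate 3 (26.9%). Estimated relative depth differed 2.55-fold between libraries, and the estimate is less certain outside DKO chow. Correlations of log2 levels were 0.947 to 0.981 within groups and 0.918 to 0.986 between groups. The first component held 35.2% of the variance and the second 15.4%.

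**Figure D1:**
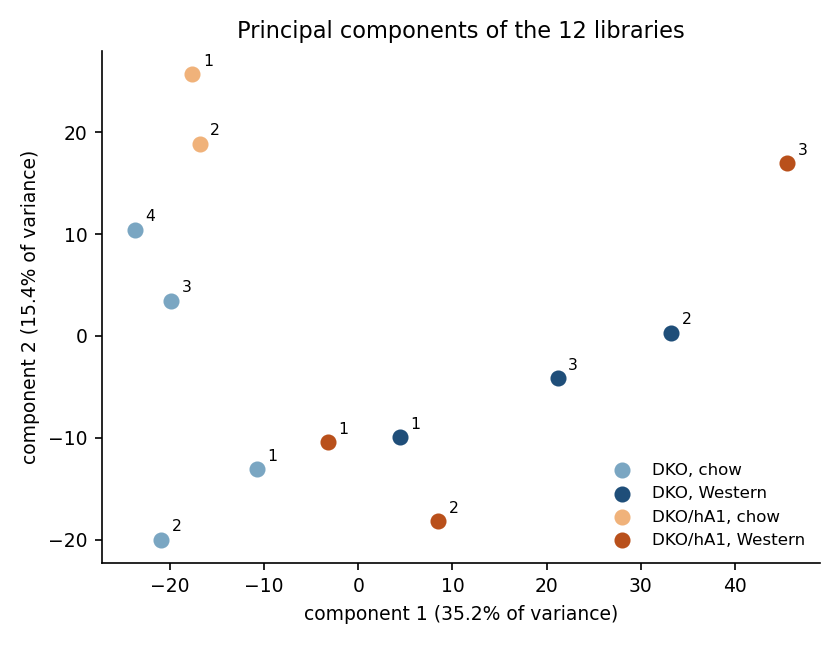
Positions of the 12 libraries on the first (35.2% of the variance) and second (15.4%) principal components of log2 FPKM, with 1 point per library and 1 colour per group. The axes are component scores without units.

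The Apoa1 and Apoe genes were read first, since the genotypes are defined by them. Apoa1 (chromosome 9, 46228630 to 46230469) stood at 40.4 ± 7.78 FPKM in DKO chow, 59.4 ± 18.6 in DKO Western diet, 227 ± 13.6 in DKO/hA1 chow and 189 ± 60.7 in DKO/hA1 Western diet livers. All 5 libraries with the transgene (122 to 239.8 FPKM) lay above all 7 without it (30.4 to 77.4), a 4.20-fold difference (exact permutation p = 0.00126, the smallest that the 792 relabellings allow). The table has no entry for human APOA1, and no value in it tells human from mouse transcripts. The signal above 0 in the DKO libraries is therefore not assigned to a source. Apoe (chromosome 7, 19696244 to 19701310) ranged from 25.7 to 89.8 FPKM without the transgene and from 12.9 to 53.2 with it (exact permutation p = 0.609). Apoe was thus above 0 in all 12 libraries. FPKM alone does not tell whether a functional transcript remains, and this signal is not assigned to a source either.

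**Figure D2:**
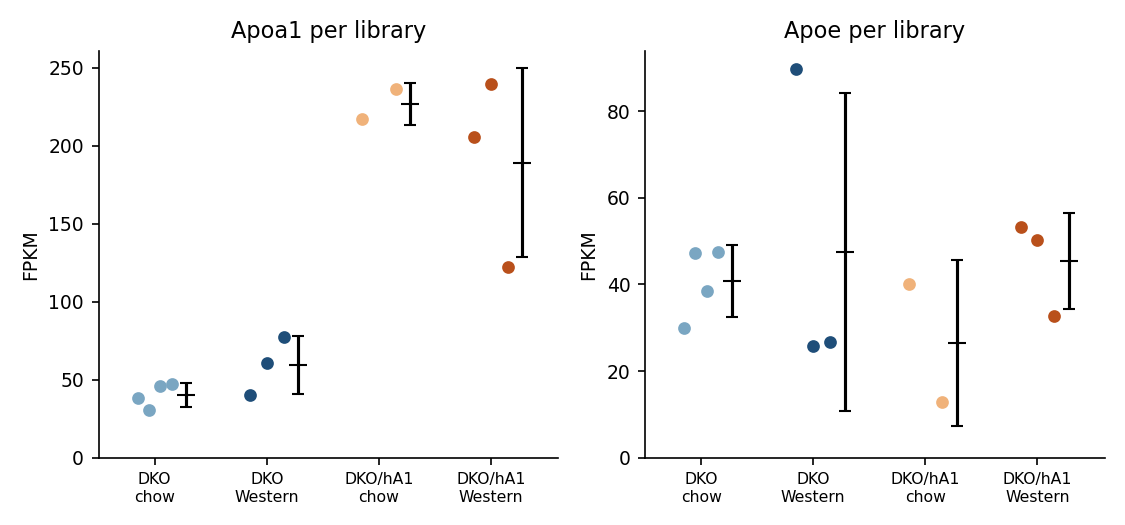
FPKM of Apoa1 and Apoe in each library, grouped by genotype and diet; points are libraries, and bars give the group mean with its SD. Apoa1 separates the 5 libraries with human APOA1 (122 FPKM or more) from the 7 without it (77.4 or less), and Apoe does not.

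The diet effect without APOA1 asked how Western diet changes the liver of mice labelled DKO, where without APOA1 means without the human transgene. The genes that fell the most included enzymes and a transporter. The glucuronosyltransferase gene Ugt1a9 (chromosome 1, 88070779 to 88220002) went from 24.3 ± 1.17 to 4.18 ± 1.85 FPKM (log2 fold change -2.41 ± 0.22, adjusted p = 0.0011). Slco1a4, an organic anion transporter, changed by -2.55 ± 0.38 and Hsd17b6, a steroid dehydrogenase, by -2.06 ± 0.31. The cytochrome P450 genes Cyp3a44 (-2.16 ± 0.22) and Cyp3a16 (-1.99 ± 0.22) fell from single-digit FPKM, and with 0.1 in place of 1 added before the log2 the changes were -3.90 and -4.13. The chemokine gene Ccl6 (chromosome 11, 83587886 to 83593087) rose from 8.31 ± 0.871 to 33.1 ± 1.65 FPKM (1.81 ± 0.19, adjusted p = 0.0022). Wfdc2, a secreted protein with a protease inhibitor fold, rose by 1.70 ± 0.21.

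In total 13 genes passed for the diet effect without APOA1, 6 higher and 7 lower, and 11 changed at least 2-fold. Others were Extl1 (1.21 ± 0.15), Uap1l1 (0.95 ± 0.15), the tight junction gene Cldn2 (0.70 ± 0.11), Raet1e, a ligand of the NKG2D receptor (-1.84 ± 0.24), and Gpr110, an adhesion receptor listed as Adgrf1 in RefSeq (-1.40 ± 0.11, and -2.96 with 0.1 added). For all 13, each of the 3 Western diet libraries lay on the same side of each of the 4 chow libraries. For an unselected gene chance gives this in 2 of 35 groupings. These genes were called from the same libraries, so the separation adds no support. Ccl6, Ugt1a9, Gpr110, Cyp3a16 and Cyp3a44 passed under each of the 27 settings tried, whereas Cldn2 passed under 11. Without DKO/hA1 Western diet replicate 3, which takes part through the shared variance and the scaling, 72 genes passed. Without DKO Western diet replicate 1, 43 passed, and 8 passed without DKO chow replicate 1, DKO Western diet replicate 2, DKO/hA1 chow replicate 1 or DKO/hA1 chow replicate 2.

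Liver acute-phase transcripts were higher on Western diet in DKO mice as a set. All 22 tested members of the acute phase list had positive fold changes with a median of 2.05. None passed over all genes and 22 passed adjusted over the list alone (camera adjusted p = 3.4e-20, and adjusted p = 0.33 with an estimated correlation). Neutrophil markers moved with them: 7 of 7 rose adjusted over the list alone and 0 over all genes (median 2.70, camera adjusted p = 1.6e-06, adjusted p = 0.37 with an estimated correlation). Both were highest in the library with the largest share of its 10 most abundant genes, with acute phase means of 9.08, 11.03 and 10.43 (log2) in DKO Western diet replicates 1, 2 and 3. Macrophage and Kupffer cell markers (16, median 0.87, 1 higher adjusted over the list alone, camera adjusted p = 1.3e-07, adjusted p = 0.47 with an estimated correlation) and lipid-associated macrophage markers (12, median 0.66, 0 adjusted over the list alone, camera adjusted p = 1.4e-05, adjusted p = 0.28 with an estimated correlation) were also higher. By exact permutation of the libraries the acute phase mean differed by 2.91 ± 0.84 (SE; p = 0.0286, the smallest that 35 relabellings allow, adjusted p = 0.127).

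Cholesterol synthesis genes were lower with Western diet in DKO livers. Of 23 members, 21 had negative fold changes, 0 passed over all genes and 3 fell adjusted over the list alone (median -0.83, camera adjusted p = 1.3e-07, adjusted p = 0.48 with an estimated correlation). Drug-metabolising enzymes (14, 3 lower adjusted over the list alone, median -0.41, camera adjusted p = 0.0019, adjusted p = 0.51 with an estimated correlation) were lower as well, and so were both sex-biased lists. Male-biased genes had a median of -1.68 (11 genes, 2 lower adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.47 with an estimated correlation) and female-biased genes one of -1.34 (6 genes, 2 lower over all genes, 3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00043, adjusted p = 0.28 with an estimated correlation). With equal totals the median of all genes was -0.186 here, the largest in size under any scaling, against -0.0048 with the trimmed mean scaling. Equal totals ended the calls of the drug-metabolising, male-biased, bile acid and T and NK cell lists. Cytokines and chemokines had a median of 0.23 (17 genes, Ccl6 over all genes, 6 higher adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.37 with an estimated correlation). Lipoprotein genes (median 0.11, 4 of 26 higher adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.28 with an estimated correlation) had a median of -0.11 with equal totals. Bile acid genes (median -0.15, camera adjusted p = 0.014), cell cycle genes (0.26, 0.025) and T and NK cell markers (-0.51, 0.025) were the other called lists, with adjusted p = 0.47, 0.69 and 0.48 with an estimated correlation. Fatty acid and triglyceride synthesis was not called (median 0.00, camera adjusted p = 0.30), nor were lipid droplets (-0.11, 0.47) or fatty acid oxidation (-0.10, 0.47). Of the 13 list calls, 9 stayed called without any 1 library, though with medians that moved. The others were T and NK cells (-0.23 without DKO chow replicate 4, ended also without its replicate 2, DKO Western diet replicate 3 or DKO/hA1 Western diet replicate 1), cell cycle (0.15 without DKO Western diet replicate 2, ended also without DKO chow replicate 1 or 3 or DKO/hA1 Western diet replicate 3), cytokines (0.17 without DKO Western diet replicate 1) and lipoproteins (0.09 without DKO Western diet replicate 3). The median of cholesterol synthesis was -0.23 and that of bile acids -0.29 without DKO Western diet replicate 1. It was -0.16 for drug-metabolising enzymes without DKO Western diet replicate 2, -0.91 for male-biased genes without its replicate 3, and 0.58 for macrophage markers and 0.070 for cytokines without DKO chow replicate 2.

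The diet effect with human APOA1 asked the same question in mice that carried the transgene. Called genes included members of the cholesterol synthesis and macrophage lists. Hmgcs1, which makes the precursor of mevalonate (chromosome 13, 119690351 to 119708260), went from 197 ± 8.83 to 25.8 ± 13.1 FPKM (-3.05 ± 0.59, adjusted p = 0.037), and Idi1, an isomerase of the same pathway, from 128 ± 19 to 13.6 ± 8.44 (-3.34 ± 0.69, adjusted p = 0.049). Cd207, the gene of langerin (chromosome 6, 83671207 to 83677857), rose from 0.867 ± 0.0555 to 17.7 ± 8.82 FPKM (3.19 ± 0.51, adjusted p = 0.023). Cd5l, a protein secreted by macrophages, rose from 92.1 ± 69.8 to 502 ± 49.4 FPKM (2.66 ± 0.47, adjusted p = 0.029). Ccl6 rose by 2.86 ± 0.22 (adjusted p = 0.00015), Lgals3, the galectin-3 gene, by 2.29 ± 0.33 and the complement gene C1qb by 2.23 ± 0.43.

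In total 152 genes passed for the diet effect with human APOA1, 115 higher and 37 lower, and 119 changed at least 2-fold. Csad, an enzyme of taurine synthesis, changed by -3.01 ± 0.44, Raet1e by -2.38 ± 0.28, Gpr110 by -2.24 ± 0.13, Ugt1a9 by -2.21 ± 0.26, Cyp2c55 by -2.18 ± 0.29 (-3.57 with 0.1 added) and the protease gene Prss8 by -1.83 ± 0.25. The largest fitted rises, Mup5 (8.30 ± 0.78) and Rpl35 (6.59 ± 0.21), rest on values far below those of every other group in both DKO/hA1 chow libraries and are uncertain, because both belong to gene families with similar copies, between which the table does not show how reads were divided. For all 152 genes the 3 Western diet libraries did not overlap the 2 chow libraries. For an unselected gene chance gives this in 2 of 10 groupings. These genes were called from the same libraries, so the lack of overlap adds no support. The count rests on single libraries: 6 genes passed without DKO/hA1 chow replicate 2, 22 without DKO/hA1 Western diet replicate 2 and 77 without its replicate 3. There were 63 without DKO chow replicate 1, 65 without DKO chow replicate 3 and 92 without DKO Western diet replicate 2. With the code number as a random block, 18 genes passed. A clock index was taken as the mean log2 level of Arntl-arm clock genes minus that of Dbp-arm ones. It was 0.21 and 0.97 in DKO/hA1 chow and -3.30, -3.63 and -1.03 in DKO/hA1 Western diet libraries, without overlap. Clock phase was thus not separated from diet in these livers, and fewer genes passed with the index in the model, as given below. Idi1 passed under 7 of the 27 settings, Hmgcs1 under 14 and Ccl6 under 26.

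Of the 23 cholesterol synthesis genes, 4 fell over all genes in DKO/hA1 livers and 20 adjusted over the list alone, and all 23 fold changes were negative (median -1.64, camera adjusted p = 1.9e-17, adjusted p = 0.25 with an estimated correlation). Besides Hmgcs1 and Idi1 these were the reductase Tm7sf2 (-1.51 ± 0.31) and Hsd17b7 (-1.19 ± 0.25). Of 16 macrophage and Kupffer cell markers, 8 rose over all genes and 15 adjusted over the list alone (median 2.00, camera adjusted p = 8.9e-18, adjusted p = 0.22 with an estimated correlation). Their mean was 3.41 (log2) in DKO/hA1 chow replicate 2 against 4.57 in replicate 1. The median was 1.35 without replicate 2 and 2.58 without replicate 1. Lyz2, the lysozyme gene, rose from 99.99 ± 56.5 to 449 ± 129 FPKM (2.23 ± 0.42), Fcgr1 by 1.61 ± 0.29 and Mpeg1 by 1.45 ± 0.28. The receptor gene Fcgr4, outside the list, rose by 2.30 ± 0.33. Of 12 lipid-associated macrophage markers, 3 rose over all genes and 9 adjusted over the list alone (median 1.26, camera adjusted p = 6.4e-09, adjusted p = 0.12 with an estimated correlation), among them the cathepsin genes Ctss (1.67 ± 0.31) and Ctsd (0.93 ± 0.18). Pltp, a phospholipid transfer protein (1.95 ± 0.39), the sterol exporter gene Abcg1 (1.56 ± 0.28) and the fatty acid receptor gene Cd36 (1.38 ± 0.27) rose too. By exact permutation the difference of list means was -1.65 ± 0.48 (SE) for cholesterol synthesis and 1.95 ± 0.46 for macrophage markers, each with p = 0.1, the smallest that 10 relabellings allow.

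Cytokines and chemokines rose in DKO/hA1 livers on Western diet (17 genes, 1 over all genes, 11 adjusted over the list alone, median 0.88, camera adjusted p = 6e-10, adjusted p = 0.058 with an estimated correlation). Interferon response genes had a median of 0.60 (19 genes, 0 over all genes and 5 adjusted over the list alone, camera adjusted p = 2.7e-06, adjusted p = 0.42 with an estimated correlation). The acute phase list (22 genes, Saa3 with 2.03 ± 0.37 over all genes and 1 adjusted over the list alone, median 1.15, camera adjusted p = 0.00011) and neutrophil markers (7 genes, 0 and 0, median 1.71, camera adjusted p = 0.033) each had adjusted p = 0.63 with an estimated correlation. Both rested on replicate 3, in which the acute phase mean was 10.93 (log2) against 7.63 and 8.35 in replicates 1 and 2. Without the 2 libraries highest in neutrophil markers, neither the acute phase list (median 0.33) nor neutrophil markers (0.34) remained called. Lower lists were oxidative stress and glutathione (14 genes, 4 lower and 1 higher adjusted over the list alone, median -0.49, camera adjusted p = 0.0012, adjusted p = 0.42 with an estimated correlation), the unfolded protein response (-0.42, camera adjusted p = 0.0051, adjusted p = 0.63 with an estimated correlation) and B cell markers (3 genes, 3 lower adjusted over the list alone, median -0.92, camera adjusted p = 0.0052, adjusted p = 0.38 with an estimated correlation). MHC class II (0.78, camera adjusted p = 0.032, adjusted p = 0.63 with an estimated correlation) and lipoprotein genes (0.13, camera adjusted p = 0.039, adjusted p = 0.25 with an estimated correlation) completed the 12 called lists. Of these calls, 7 stayed without any 1 library, but the interferon median was 0.37 without DKO/hA1 Western diet replicate 1. Besides acute phase and neutrophil markers, the others were MHC class II (0.63 without DKO/hA1 chow replicate 2), the unfolded protein response (-0.11 without DKO/hA1 Western diet replicate 2) and lipoproteins (0.06 without DKO/hA1 Western diet replicate 1). The first 2 of these calls ended without any of 3 libraries, DKO/hA1 chow replicate 2 and DKO/hA1 Western diet replicates 1 and 2. The lipoprotein call ended also without DKO/hA1 chow replicate 1, and the neutrophil call also without either DKO/hA1 chow library.

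The diet effect averaged over genotypes used all 12 libraries and was added after seeing the data. Cyp3a11, a major drug-metabolising cytochrome P450 (chromosome 5, 145854607 to 145879854), stood at 1333 ± 330.5 FPKM in DKO chow and 69.1 ± 57.9 in DKO Western diet, and at 1072 ± 213 and 189.5 ± 139 in DKO/hA1 livers (log2 fold change -4.07 ± 0.79, adjusted p = 0.022). The acute-phase genes Saa2 (5.43 ± 1.10), Lcn2 (4.92 ± 0.98) and Orm2 (4.72 ± 1.01) had the largest rises, unevenly spread. Saa2 was 4021, 42634 and 21994 FPKM in DKO Western diet replicates 1, 2 and 3, and 446, 1051 and 36968 in DKO/hA1 Western diet replicates 1, 2 and 3. In all 456 genes passed, 318 higher and 138 lower (159 at least 2-fold), and with equal totals the split was 181 higher and 240 lower. With the code number as a random block, 39 genes passed. Genes named below for this comparison differed in how often they passed. Of 26 settings, Pcx passed under 7, Scd2 and Selenbp2 under 8, Gstm3 and Psmb8 under 9, and Fabp4, Il1rn and Ifi27l2a under 11. Ccl6, Cd207, Ugt1a9 and Raet1e passed under all 26. There were 34 without DKO/hA1 chow replicate 2, 278 without its replicate 1, 234 without DKO Western diet replicate 2 and 245 without DKO chow replicate 3.

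Of 23 cholesterol synthesis genes, 11 fell over all genes on Western diet and 20 adjusted over the list alone (median -1.14, camera adjusted p = 2e-15, adjusted p = 0.32 with an estimated correlation). They included Idi1 (-2.54 ± 0.45), Tm7sf2 (-1.28 ± 0.20), Stard4, a sterol transfer protein (-1.09 ± 0.19), and Hsd17b7 (-1.01 ± 0.16). Macrophage and Kupffer cell markers rose in 10 of 16 over all genes and 16 adjusted over the list alone (median 1.43, camera adjusted p = 2e-15, adjusted p = 0.22 with an estimated correlation), with Cd5l at 1.83 ± 0.31 and C1qa at 1.31 ± 0.22. Lipid-associated macrophage markers rose in 5 of 12 and 10 (median 0.93, camera adjusted p = 5.1e-09, adjusted p = 0.12 with an estimated correlation), among them Lgals3 (1.5 ± 0.22) and the receptor gene Trem2 (1.49 ± 0.32). Lipoprotein and sterol efflux genes rose in 4 of 26 and 6 (median 0.23, camera adjusted p = 0.014, adjusted p = 0.22 with an estimated correlation): Pltp (1.70 ± 0.25), Abcg1 (1.09 ± 0.18), Abcg5, a biliary sterol exporter (0.96 ± 0.20), and Scarb1, the receptor for high-density lipoprotein (0.59 ± 0.10). Cytokines and chemokines rose in 4 of 17 and 9 (median 0.56, camera adjusted p = 1.1e-07, adjusted p = 0.12 with an estimated correlation), namely Ccl6 (2.34 ± 0.15), Il1rn (1.46 ± 0.34), Tlr2 (0.93 ± 0.18) and Icam1 (0.68 ± 0.12). These 5 lists also passed by exact permutation of the libraries within genotype (350 relabellings, p = 0.00286 each, the smallest possible, adjusted p = 0.0177 over 31 lists). The differences were -1.21 ± 0.32 (SE), 1.41 ± 0.30, 1.02 ± 0.18, 0.30 ± 0.05 and 0.72 ± 0.10 in the order named. The permutation treats libraries as exchangeable, but libraries with the same code number correlated (consensus correlation 0.565). Code numbers were not shared between diets, so these p may be too small and do not separate diet from a batch that followed the codes.

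**Figure D3:**
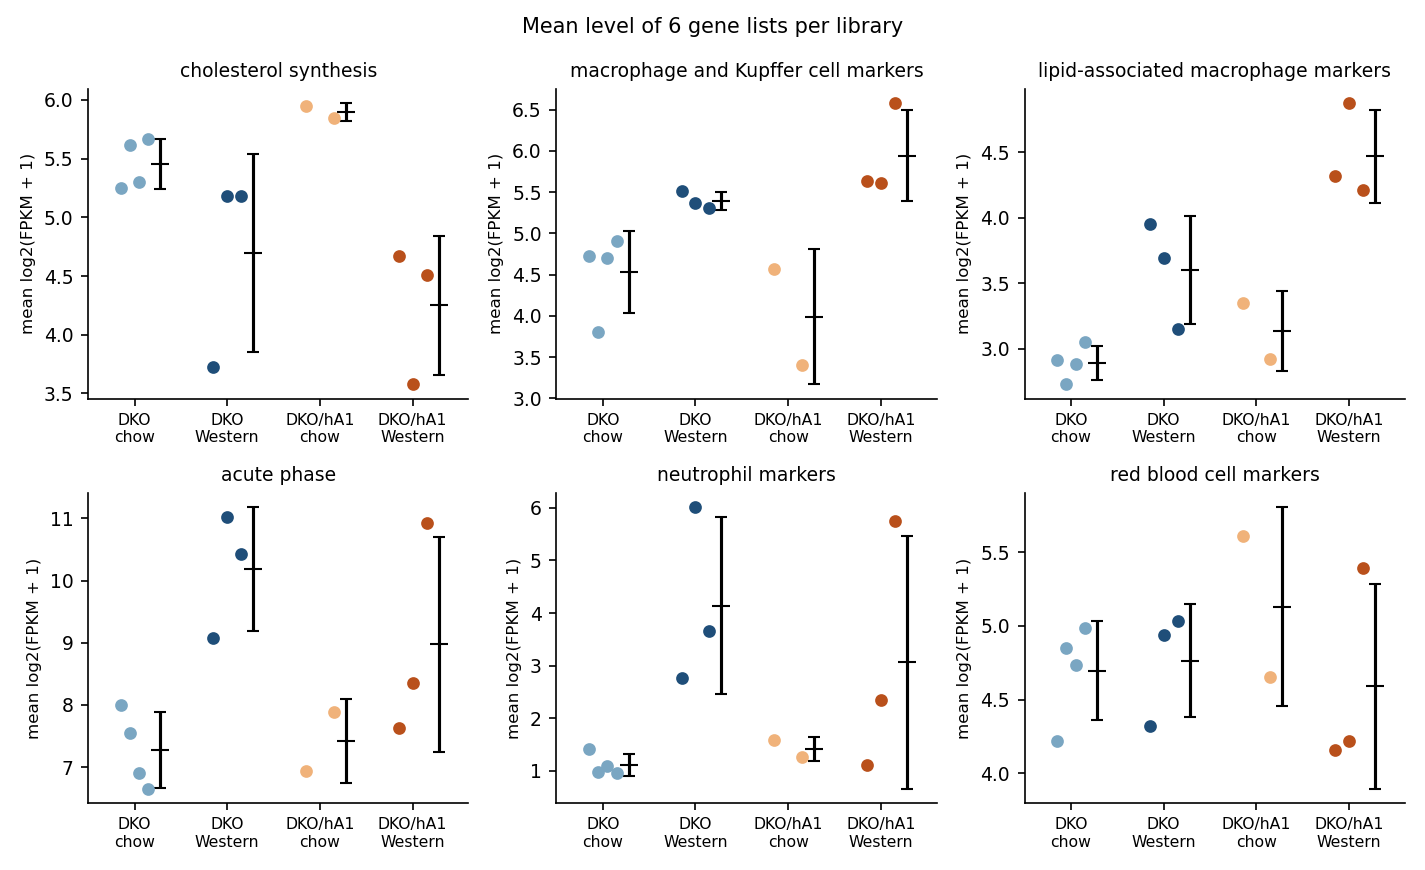
Mean log2 (FPKM + 1) of gene lists in each of the 12 libraries, with 1 point per library and bars giving the group mean with its SD. Cholesterol synthesis was lower and macrophage and Kupffer cell markers were higher on Western diet, and acute phase and neutrophil levels were highest in DKO Western diet replicate 2 and DKO/hA1 Western diet replicate 3.

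The acute phase list rose in 6 of 22 over all genes and 18 adjusted over the list alone on Western diet (median 1.66, camera adjusted p = 4.5e-13, adjusted p = 0.41 with an estimated correlation), including Orm3 (4.15 ± 0.73) and Saa3 (1.73 ± 0.24). Neutrophil markers rose with it in 7 of 7 adjusted over the list alone and 0 over all genes (median 2.17, camera adjusted p = 9.1e-05, adjusted p = 0.43 with an estimated correlation). The exact permutation p, with the limit on code numbers given above, was 0.0114 (adjusted p = 0.059) and 0.02 (adjusted p = 0.0775). Drug-metabolising enzymes fell in 3 of 14 over all genes and 4 adjusted over the list alone, but the list was not called (median -0.05, camera adjusted p = 0.13). These were Cyp3a11, the carboxylesterase gene Ces2a (-2.07 ± 0.41) and Cyp2c55 (-1.74 ± 0.19, and -2.99 with 0.1 added). In the oxidative stress and glutathione list the glutathione transferase genes Gsta2 (-2.17 ± 0.41), Gsta1 (-1.79 ± 0.33) and Gstm3 (-1.71 ± 0.38) fell, and adjusted over the list alone 6 fell and 2 rose (median -0.21, camera adjusted p = 0.029, adjusted p = 0.58 with an estimated correlation). The interferon response (2 of 19 over all genes and 3 adjusted over the list alone, median 0.31, camera adjusted p = 0.0027, adjusted p = 0.58 with an estimated correlation) included Ifi27l2a (1.00 ± 0.24) and Psmb8 (0.54 ± 0.13). Male-biased genes (11, median -1.20, camera adjusted p = 0.0064, adjusted p = 0.51 with an estimated correlation) included Selenbp2 (-1.83 ± 0.43) and Ugt2b38 (-0.92 ± 0.18), and female-biased genes (6, median -0.64, camera adjusted p = 0.046, adjusted p = 0.43 with an estimated correlation) Cyp3a44 (-1.68 ± 0.17) and Cyp3a16 (-1.59 ± 0.17), which changed by -2.86 and -3.14 with 0.1 added. The calls of the oxidative stress and both sex-biased lists ended with equal totals. B cell markers fell in 3 of 3 adjusted over the list alone and 0 over all genes (median -0.59, camera adjusted p = 0.011, adjusted p = 0.41 with an estimated correlation). Of the 12 list calls, 8 stayed without any 1 library. Without DKO/hA1 Western diet replicate 3 the median was -0.78 for male-biased and -0.27 for female-biased genes. The interferon (0.26), lipoprotein (0.17) and oxidative stress calls (-0.16) ended without DKO/hA1 Western diet replicate 1, and the female-biased call without DKO chow replicate 1 or 2, DKO Western diet replicate 1 or 2 or DKO/hA1 Western diet replicate 1, the highest adjusted p being 0.076 without DKO chow replicate 2.

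Fatty acid and triglyceride synthesis was not called for diet averaged over genotypes (22 genes, median 0.03, camera adjusted p = 0.79), although the desaturase gene Scd2 (0.60 ± 0.15) rose. Lipid droplets and uptake was not called either (14 genes, median 0.01, camera adjusted p = 0.36), with rises of Cd36 (1.06 ± 0.17) and the fatty acid binding protein gene Fabp4 (0.98 ± 0.23). In gluconeogenesis (13 genes, median -0.06, camera adjusted p = 0.79) Pcx rose by 0.40 ± 0.10 (0.24 and not called with equal totals) and the glutaminase gene Gls2 changed by -0.71 ± 0.12. Fatty acid oxidation (median 0.05, camera adjusted p = 0.66), bile acids (-0.14, 0.097), MHC class II (0.46, 0.095), extracellular matrix (0.09, 0.36), the unfolded protein response (-0.09, 0.36), clock (0.28, 0.50) and cell cycle genes (0.11, 0.43) were not called, with 0 members past the threshold over all genes. Nor were markers of T and NK cells (-0.14, 0.88), endothelium (-0.05, 0.90), stellate cells (0.07, 0.67) and cholangiocytes (-0.46, 0.079), immediate early genes (0.11, 0.43) or Y chromosome genes with Xist (-0.10, 0.45), in the same order of values. Hepatocyte markers had a median of -0.12 (11 genes, 0 over all genes, 3 lower adjusted over the list alone, camera adjusted p = 0.24), and red blood cell markers one of -0.20 (camera adjusted p = 0.39). Other named genes were Cd207 (2.95 ± 0.34), Acnat2, a peroxisomal acyltransferase (2.33 ± 0.49), Slc13a3, a dicarboxylate transporter (2.06 ± 0.31), Agxt2l1 (listed as Etnppl in RefSeq, -2.20 ± 0.33), Ugt1a9 (-2.31 ± 0.17), Raet1e (-2.11 ± 0.18) and Slco1a4 (-2.09 ± 0.30). Rpl35 (3.40 ± 0.14) is uncertain for the reason given above. Fcgr1 (1.16 ± 0.19), Mpeg1 (1.21 ± 0.18), Ctss (1.16 ± 0.20) and Ctsd (0.69 ± 0.12) rose as they did in DKO/hA1 livers alone.

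Diet effects were set side by side to ask whether human APOA1 alters the response to Western diet. Across genes, which are not independent replicates, the fold changes of the genotypes correlated at r = 0.558. Simulated unchanged groups gave 0.002, but their genes were drawn independently. Real genes move together, so the simulation does not show what r unchanged livers would give. Of the 160 genes that passed in either genotype, 152 (95%) had the same sign in both, against 64.1% of all genes tested. Ccl6 and Extl1 rose in both, and Ugt1a9, Raet1e and Gpr110 fell in both, where independent sets of the same size would share 0.060 higher and 0.022 lower genes. Both comparisons use the same variance estimate for a gene, which can favour a low-variance gene in both. The values for independent sets are therefore no measure of chance. The median absolute change of the 160 genes was 0.63 without APOA1 and 1.38 with it, but most were selected in DKO/hA1 livers, which favours the larger value there. The difference itself passed for 2 genes in limma, Mup5 (8.52 ± 1.02, adjusted p = 0.033) and Rpl35 (6.37 ± 0.28, adjusted p = 7.7e-07), both uncertain for the reason given above, and 563 had an unadjusted p under 0.05. There were 8 without DKO/hA1 Western diet replicate 3 and 1 without any other library but DKO Western diet replicate 1. Without a level filter 8 genes passed. With the filter and all libraries, no difference between genotypes was shown for any other single gene. Without DKO/hA1 Western diet replicate 3, r was 0.323.

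**Figure D4:**
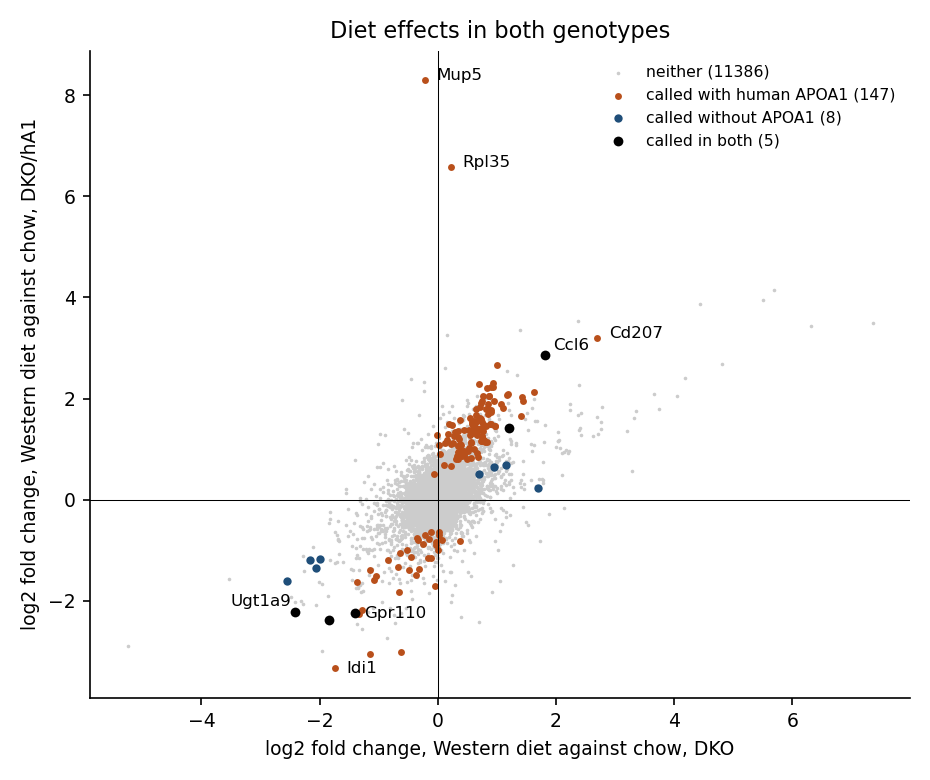
Log2 fold change of Western diet over chow in DKO (horizontal axis) and DKO/hA1 livers (vertical axis), with 1 point per gene tested and genes called in either comparison marked. Across genes r was 0.558, and 152 of the 160 called genes had the same sign, against 64.1% of all genes.

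At the preset correlation, camera called several lists for a different diet response between genotypes, but none passed with an estimated correlation. Libraries were not permuted for the interaction, so a difference of these lists is not established. The difference (DKO/hA1 minus DKO) had a median of -0.96 for cholesterol synthesis (camera adjusted p = 4.7e-07) and 1.19 for macrophage and Kupffer cell markers (7.4e-09), with adjusted p = 0.51 and 0.50 with an estimated correlation. Cytokines (0.66, camera adjusted p = 1.1e-05), interferon response (0.45, 1.5e-06) and lipid-associated macrophage markers (0.53, 0.0019) were higher, with adjusted p = 0.32, 0.50 and 0.50 with an estimated correlation. The acute phase list was lower (-1.37, camera adjusted p = 4.9e-05, adjusted p = 0.65 with an estimated correlation) and so were the unfolded protein response (-0.53, 1.1e-05, 0.51) and oxidative stress and glutathione (-0.42, 0.0030, 0.51), given as median, camera adjusted p and adjusted p with an estimated correlation. Over these lists no gene passed over all genes, and 1 passed adjusted over the list alone, in the lipid-associated macrophage list. The macrophage difference rests on DKO/hA1 chow replicate 2, with a list mean of 3.41 (log2) against 4.57 in replicate 1, and was 0.54 without it and 1.92 without replicate 1. The cholesterol difference was -0.50 without DKO/hA1 Western diet replicate 2, the acute phase difference -0.46 without DKO/hA1 Western diet replicate 1, and the lipid-associated macrophage difference 0.28 without DKO/hA1 Western diet replicate 2. The unfolded protein response difference was -0.34 without DKO/hA1 Western diet replicate 2. The oxidative stress call ended without DKO Western diet replicate 3 (-0.31). The clock index did not overlap between the diets in DKO/hA1 livers, though it did in DKO livers. Clock phase is therefore not separated from diet in these differences.

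The genotype effect on chow asked what the human transgene changes without a high-fat diet. Apoa1 was higher (2.46 ± 0.29, adjusted p = 0.0071). Dio1, the deiodinase that activates thyroid hormone (chromosome 4, 107291465 to 107307168), was lower, with 66.6 ± 13.0 FPKM in DKO and 22.0 ± 6.08 in DKO/hA1 livers (-1.59 ± 0.23, adjusted p = 0.030). Gpr110 rose from 2.12 ± 0.121 to 6.17 ± 0.661 FPKM (1.18 ± 0.12, adjusted p = 0.0026) and Synj2, a phosphoinositide phosphatase gene, by 1.09 ± 0.16 (1.76 and not called with 0.1 added). In all 9 genes passed, 6 higher and 3 lower, but 1 passed without the 2 libraries highest in intestine markers, DKO chow replicate 4 and DKO/hA1 chow replicate 1. The remaining ones were Gm17746 (1.88 ± 0.19), Tox2 (1.24 ± 0.19) and Gprc5b (0.96 ± 0.14), named because the count is small, and the uncertain Mup5 (-8.87 ± 0.74) and Rpl35 (-6.48 ± 0.20). Both DKO/hA1 chow libraries carried the same code number, and 2 genes passed without replicate 1 or without replicate 2. There were 33 without DKO/hA1 Western diet replicate 3, 15 without its replicate 1, and 5 without DKO chow replicate 3 or DKO Western diet replicate 2 or 3. Dio1 and Synj2 each passed under 12 of 27 settings, and Apoa1 and Gpr110 each under 23.

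On chow the unfolded protein response was higher with human APOA1 (19 genes, 18 positive, 0 adjusted over the list alone, median 0.50, camera adjusted p = 2.4e-06, adjusted p = 0.56 with an estimated correlation). Oxidative stress and glutathione genes (14, 3 adjusted over the list alone, median 0.48, camera adjusted p = 9.1e-05, adjusted p = 0.54 with an estimated correlation) and extracellular matrix genes (19, 2 adjusted over the list alone, median 0.34, camera adjusted p = 0.00011, adjusted p = 0.68 with an estimated correlation) were higher too. Macrophage and Kupffer cell markers were lower (16, 0 adjusted over the list alone, median -0.64, camera adjusted p = 0.00022, adjusted p = 0.69 with an estimated correlation), and so were fatty acid oxidation (24, median -0.35, 0.00022, 0.69), bile acid (19, -0.38, 0.00058, 0.54) and drug-metabolising genes (14, -0.51, 0.0020, 0.68), given in the same order. Cholesterol synthesis (0.50, 0.0037, 0.71), B cell markers (0.53, 0.010, 0.56), fatty acid synthesis (0.38, 0.012, 0.71), cell cycle (0.24, 0.016, 0.71), immediate early genes (0.53, 0.020, 0.68) and lipoproteins (-0.15, 0.020, 0.54) made up the 13 called lists. The macrophage call rests on 1 library: DKO/hA1 chow replicate 2 had a mean of 3.41 (log2), while replicate 1 (4.57) lay inside the DKO chow range (3.80 to 4.90), and the median was 0.076 without replicate 2 and -1.36 without replicate 1. Without DKO/hA1 chow replicate 2 the cell cycle (0.14) and immediate early calls (0.14) ended too, and without replicate 1 those of extracellular matrix (0.15) and fatty acid synthesis (0.37), with lipoproteins ending without replicate 1 or 2. The immediate early call ended also without DKO chow replicate 1. No member of a list passed over all genes. Adjusted over the list alone, 1 rose and 4 fell among drug-metabolising genes, 1 rose and 1 fell in fatty acid oxidation and in bile acids, and 1 rose in fatty acid synthesis and among immediate early genes. DKO chow replicate 4 and DKO/hA1 chow replicate 1 also held intestine transcripts, with means of 3.34 and 2.16 (log2) against 0.65 to 1.71 elsewhere. The 15 relabellings of the chow libraries allow no exact permutation p below 0.0667.

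The genotype effect on Western diet asked what human APOA1 changes in livers exposed to the high-fat diet. No gene passed in limma (0 of 11546, with 675 at an unadjusted p under 0.05, 422 higher and 253 lower, and a smallest adjusted p of 0.225). The 3 positive genes with the smallest p were Htra1, a secreted protease (1.43 ± 0.108 against 3.64 ± 0.347 FPKM, 0.95 ± 0.14), Apoa1 (1.68 ± 0.27, adjusted p = 0.37) and Bcl2a1a (1.07 ± 0.19, adjusted p = 0.44). The 3 negative ones were Dpy19l3 (-0.76 ± 0.14), Mettl1 (-0.65 ± 0.14) and Rpl29 (-0.82 ± 0.18). With 3 against 3 libraries no exact permutation p can fall below 0.1.

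As sets, lipid-associated macrophage markers were higher with human APOA1 on Western diet (12 genes, all positive, 0 over all genes and 8 adjusted over the list alone, median 0.88, camera adjusted p = 2.1e-09, adjusted p = 0.098 with an estimated correlation). Extracellular matrix genes (19, 0 and 4, median 0.46, camera adjusted p = 4.7e-10, adjusted p = 0.27 with an estimated correlation), interferon response (19, 0 and 0, 0.49, 1.5e-08, 0.27), cytokines (17, 0 and 0, 0.53, 2.6e-07, 0.098) and MHC class II (8, 0 and 0, 0.74, 1.2e-05, 0.35) were higher as well, in the same order of values. So were Kupffer cell markers (0.52, camera adjusted p = 2e-05, adjusted p = 0.47 with an estimated correlation), T and NK cell markers (0.57, 0.00026, 0.27), stellate cell markers (0.40, 0.00026, 0.39), female-biased genes (0.85, 0.00054, 0.24), immediate early genes (0.66, 0.00072, 0.29) and endothelial markers (0.39, 0.034, 0.78). Lower lists were acute phase (-1.11, camera adjusted p = 2e-07, adjusted p = 0.47 with an estimated correlation), cholesterol synthesis (-0.39, 6.8e-05, 0.60), lipoproteins (-0.23, 0.026, 0.26), neutrophil markers (-1.14, 0.031, 0.74) and bile acids (-0.13, 0.034, 0.47), whose median was 0.03 with equal totals. Adjusted over the list alone, 2 T and NK cell markers and 1 immediate early gene were higher, and 0 in the other lists named after MHC class II. Without the libraries highest in neutrophil markers, which are 1 of each genotype, the Kupffer cell call ended (median 0.26). Of the 16 list calls, 7 stayed without any 1 library. The acute phase median ran from -0.61 without DKO/hA1 Western diet replicate 1 to -1.85 without its replicate 3, and medians were smaller for interferon (0.31 without DKO Western diet replicate 3), cytokines (0.35 without DKO/hA1 Western diet replicate 3) and female-biased genes (0.52 without DKO Western diet replicate 2). Without DKO/hA1 Western diet replicate 3 the Kupffer cell (0.20), bile acid (0.04) and lipoprotein calls ended, and without its replicate 1 the T and NK cell (0.37), immediate early (0.27) and neutrophil calls (0.013). The bile acid call ended also without DKO Western diet replicate 1 or 3 or DKO chow replicate 4, the lipoprotein call without DKO Western diet replicate 3 or DKO/hA1 Western diet replicate 2, and the neutrophil call without replicate 2 of either genotype on Western diet. The neutrophil median was -2.67 and the female-biased median 1.298 without DKO/hA1 Western diet replicate 3. The cholesterol call ended without DKO/hA1 Western diet replicate 2 (-0.23) and without DKO Western diet replicate 2 or 3 (-0.16 without replicate 3), and its median was -0.90 without DKO Western diet replicate 1. Without DKO Western diet replicate 3 the stellate cell call (0.25) ended too. The endothelial call ended without any of 5 of the 6 libraries compared, all but DKO Western diet replicate 1 (0.04 without DKO Western diet replicate 3).

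For the genotype effect on Western diet against the diet effect without APOA1, r across genes was -0.330. The comparisons share the DKO Western diet libraries. Unchanged groups simulated with shared libraries, with genes drawn independently, gave -0.533 (-0.571 to -0.477). The covariance was -0.0332 against a simulated -0.0282 (-0.0332 to -0.0241), so no opposition beyond the shared libraries was shown. The r ranged from -0.573 without DKO/hA1 Western diet replicate 3 and -0.569 without DKO Western diet replicate 1 to -0.176 and -0.0609 without DKO/hA1 Western diet replicates 2 and 1.

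The genotype effect averaged over diets, added after seeing the data, gave 13 genes, 9 higher and 4 lower. Genes named as its largest changes also had to show no overlap between diets within each genotype. Apoa1 (2.07 ± 0.20, adjusted p = 0.0022), Scd2 (0.94 ± 0.15), Gpr110 (0.77 ± 0.09), Htra1 (0.73 ± 0.10) and Synj2 (0.68 ± 0.11) were higher (the last 3 by 1.28, 1.11 and 1.09 with 0.1 added, where Synj2 was not called), and Dio1 (-1.01 ± 0.16), the cytochrome P450 gene Cyp2d40 (-0.76 ± 0.12) and the uncertain Rpl35 (-3.29 ± 0.14) lower. Extracellular matrix genes were higher in 8 of 19 adjusted over the list alone and 0 over all genes (median 0.38, camera adjusted p = 1.7e-10, adjusted p = 0.38 with an estimated correlation), and lipid-associated macrophage markers in 2 of 12 (median 0.44, camera adjusted p = 4.2e-06, adjusted p = 0.29 with an estimated correlation). By exact permutation within diet (300 relabellings) the differences were 0.46 ± 0.16 (SE; p = 0.0267) and 0.56 ± 0.18 (p = 0.01), each with adjusted p = 0.258. Of the other called lists, MHC class II (0.51, camera adjusted p = 0.00056), immediate early (0.61, 0.00066), oxidative stress (0.29, 0.00091), unfolded protein response (0.18, 0.0019), stellate cell (0.29, 0.0025), interferon (0.23, 0.0059), cytokine (0.32, 0.018), fatty acid synthesis (0.18, 0.026) and B cell genes (0.44, 0.036) were higher. Fatty acid oxidation (-0.27, 0.0003), bile acid (-0.29, 0.0003), lipoprotein (-0.17, 0.0019), drug-metabolising (-0.36, 0.0059) and acute phase genes (-0.44, 0.0059) were lower. With an estimated correlation their adjusted p lay between 0.258 (lipoproteins) and 0.694 (acute phase). Of the 16 list calls, 7 stayed without any 1 library, those of extracellular matrix, lipid-associated macrophages, MHC class II, bile acids, lipoproteins, immediate early genes (0.35 without DKO/hA1 Western diet replicate 1) and oxidative stress (0.091 without DKO Western diet replicate 2). The calls of fatty acid synthesis (0.035), acute phase (-0.17) and interferon (0.13) ended without DKO/hA1 Western diet replicate 1, and those of the unfolded protein response (0.058) and drug-metabolising genes (-0.21) without its replicate 3. Those of fatty acid oxidation (-0.16) and stellate cells (0.16) ended without DKO Western diet replicate 3, as did the interferon and drug-metabolising calls, and that of the unfolded protein response also without DKO/hA1 chow replicate 2. The B cell call ended without any of 8 of the 12 libraries (0.40 without DKO Western diet replicate 1), all but DKO chow replicate 4, DKO Western diet replicate 2, DKO/hA1 chow replicate 1 and DKO/hA1 Western diet replicate 2. The cytokine call ended without any of 4, DKO Western diet replicate 3, DKO/hA1 Western diet replicates 1 and 3 and DKO/hA1 chow replicate 1 (0.22). The fatty acid synthesis call ended also without DKO Western diet replicate 1 or 2, DKO chow replicate 3 or DKO/hA1 chow replicate 1, and the acute phase call also without replicate 2 of either genotype on Western diet or DKO/hA1 chow replicate 1. Scd2 passed under 3 of 26 settings, Cyp2d40 and Synj2 under 5 each and Dio1 under 6. Htra1 passed under 17, Gpr110 under 22 and Apoa1 under 26. There were 2 genes without DKO/hA1 chow replicate 1, 4 without its replicate 2, 5 without DKO chow replicate 2 or DKO Western diet replicate 3, 6 without DKO chow replicate 3, 7 without DKO Western diet replicate 2 and 8 without DKO/hA1 Western diet replicate 2.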

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

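The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the libraries, whose reading was set before they were run.

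In the DKO chow group, 9 of 108 results had 1 library further from the others than Dixon's 95% critical value for 4 libraries, where chance gives a share of 0.05. Each value is the gap to the nearest library as a share of the range. In replicate 2 the macrophage genes Cd5l (0.915), C1qb (0.921) and Lyz2 (0.8293) and the endothelial list (0.864) were low, with Cd5l at 6.24 (log2) against 7.35 to 7.45 and the endothelial mean at 2.63 against 3.73 to 3.90. Slc13a3 was low in replicate 3 (0.850) and Agxt2l1 in replicate 1 (0.943). Gsta2 (0.884), the MHC class II list (0.831) and the cell cycle list (0.895) were high in replicate 4, the library with the most intestine transcripts. No explanation was tested for these.

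By the interaction, Mup5 (8.52), Rpl35 (6.37) and 13 gene lists were called for a diet effect that differed between genotypes. Both genes are uncertain for the reason given above, and the lists were called by camera at the preset correlation. The lists with a higher diet effect with human APOA1, by median difference, were macrophage and Kupffer cells (1.19), female-biased genes (1.16, camera adjusted p = 0.0015), endothelium (0.81, 0.0033), T and NK cells (0.75, 0.00015), cytokines (0.66), drug-metabolising enzymes (0.54, 0.05), lipid-associated macrophages (0.53) and interferon response (0.45). Those with a lower one were acute phase (-1.37), cholesterol synthesis (-0.96), unfolded protein response (-0.53), oxidative stress and glutathione (-0.42) and cell cycle (-0.26, 0.019). None passed with an estimated correlation. The endothelial difference rests on DKO/hA1 chow replicate 2, whose list mean was 2.48 (log2) against 3.89 in replicate 1, and was 0.076 without it; its call ended without DKO Western diet replicate 3 as well. The T and NK cell difference was 0.42 without DKO chow replicate 4. The drug-metabolising call ended without any of 7 single libraries, namely replicates 1 and 2 of DKO chow, of DKO/hA1 chow and of DKO/hA1 Western diet, and replicate 2 of DKO Western diet. The cell cycle call ended without any of 4, DKO Western diet replicate 2, DKO/hA1 Western diet replicates 1 and 2 and DKO/hA1 chow replicate 2.

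Other splits of the same libraries were counted. For diet without APOA1, 1 of 35 splits, the real one, gave as many genes (13, highest other 2). This argues against chance as the source of the count, though 35 splits allow no smaller share. For diet averaged over genotypes, 1 of 100 splits drawn from 350 did (456, highest other 4), which argues against chance there too. Neither excludes a batch that followed the code numbers, none of which was shared between diets. For genotype averaged over diets, 10 of 100 splits drawn from 300 gave as many (13, highest other 228), so chance cannot be excluded, and the larger counts point to a structure of the libraries other than genotype. For genotype on Western diet the 10 splits are too few for a share under 0.05 (0 genes, highest other 291, and all 10 gave at least 0). The split with 291 set DKO replicate 1 with DKO/hA1 replicates 1 and 2 against the other 3, which points to a structure that follows the neutrophil and acute-phase levels.

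Acute-phase and neutrophil transcripts were high on Western diet. More blood in the tissue is argued against by the red blood cell list, which differed by -0.24 ± 0.30 (SE) between diets, while neutrophil markers differed by 2.34. A shift of the scaling by a few abundant genes is argued against too, since over 4 scalings the lowest acute-phase difference was 2.08 ± 0.58. Diet remains a candidate explanation (exact permutation p = 0.0114), but 0 code numbers were shared between diets, so diet and a batch that followed the codes cannot be told apart. Infection or other illness of single mice was not tested.

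On chow, 9 genes passed between genotypes. With a clock index in the model their absolute fold changes had a median ratio of 0.977 to those without, and 5 of 9 stayed called. Calls ended for Dio1 (-1.59 ± 0.23 to -1.46 ± 0.24), Tox2 (1.24 ± 0.19 to 1.07 ± 0.17), Gprc5b (0.96 ± 0.14 to 0.94 ± 0.16) and Synj2 (1.09 ± 0.16 to 1.09 ± 0.18), with little change in size, so clock phase is not the whole cause. Without the 2 libraries highest in intestine markers, DKO chow replicate 4 and DKO/hA1 chow replicate 1, the median ratio was 1.01 but 1 of 9 stayed called. Apoa1 went from 2.46 ± 0.29 to 2.60 ± 0.42 and Dio1 from -1.59 ± 0.23 to -1.32 ± 0.31. Gpr110 went from 1.18 ± 0.12 to 1.08 ± 0.18 and Gm17746 from 1.88 ± 0.19 to 1.66 ± 0.26. Tox2 went from 1.24 ± 0.19 to 1.44 ± 0.25 and Gprc5b from 0.96 ± 0.14 to 1.01 ± 0.20. Synj2 went from 1.09 ± 0.16 to 1.01 ± 0.23 and Mup5 from -8.87 ± 0.74 to -8.95 ± 1.09. SE were larger and 1 DKO/hA1 chow library was left, so intestine tissue stays open for genes other than Apoa1. For Apoa1 it is argued against. The 3 DKO/hA1 Western diet libraries had intestine means of 0.73 to 0.86 (log2) and Apoa1 of 122 FPKM or more. Every DKO library had 77.4 or less, DKO chow replicate 4 (intestine mean 3.34) included. Of the 9 genes, 7 lie outside the Mup and ribosomal protein families and stayed called without those families. Leaving out those families changes the values of other genes only through the scaling. It therefore cannot decide whether these 7 genes share reads with other copies. Only 1 DKO chow library shared the code number of the 2 DKO/hA1 chow libraries, so genotype and that code cannot be told apart in the genes other than Apoa1. For Apoa1 the code is argued against, since all 3 libraries with human APOA1 and another code number lay above every library without it.

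Some abundant genes were listed at 0 throughout a group. Alb was at 0 in 9 libraries and averaged 15085 FPKM in the 3 DKO Western diet libraries, and Trf was at 0 in the 3 DKO/hA1 Western diet libraries and averaged 9110 in 9. In 17 of 20 abundant genes with any 0 the zeros followed whole groups, but 15 of these shared 1 pattern, and a difference between the groups would give the same count. Estimates that failed group by group in the deposited table and such a difference therefore cannot be told apart by it. Rpl31-ps12, left out of the tests, followed diet. It had at most 0.188 FPKM in every chow library and 183 to 250 in every Western diet library. Whether its estimation differed between the diets was not tested, so a difference in processing along the diet comparison stays open. For Alb and Trf, absent liver transcripts are argued against by the hepatocyte list, which differed by -0.16 ± 0.09 between libraries with and without the zeros. For Rpl35 a general change is argued against by a median of 0.0091 (scaled median absolute deviation 0.127) over 82 other ribosomal protein genes. For Mup5, 14 of 20 Mup genes were above 0 in the DKO/hA1 chow libraries and at 0 in the other groups, so reads shared with near-identical copies may explain its fall there.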

How the results depend on the processing

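Chosen after seeing the data were the averaged comparisons with all their alternatives, and for every comparison the alternatives with an added 0.1, values as deposited, a clock index, array weights, and fits less neutrophil-high or intestine-high libraries or less Mup and ribosomal protein genes. The planned edgeR, DESeq2 and voom tests were not used, since they need counts. The trial fits seen before the settings were fixed make the choice of settings itself dependent on the data.

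With equal totals 69 genes passed for diet with human APOA1, 1 for the interaction and 21 for the genotype effect averaged over diets (averaged genotype). Without a level filter 27 passed for genotype on chow and 8 for the interaction. A replicate block gave 85 for diet with human APOA1, 1 for the interaction, 298 for the diet effect averaged over genotypes (averaged diet), 6 for averaged genotype and an agreement r of 0.431. Replicate numbers do not pair the mice (mean residual r 0.025 within numbers, -0.011 between). The code number as a random block (correlation 0.565) gave 18 for diet with human APOA1, 28 for genotype on chow and 39 for averaged diet. A fold threshold of 1.2 gave 8 for diet without APOA1, 25 with it, 5 for genotype on chow, 61 for averaged diet and 3 for averaged genotype, as a stricter hypothesis must. With only the 2 groups compared, 11 passed for diet with human APOA1 and 44 for genotype on chow. Adding 0.1 gave 3 for genotype on chow and 7 for averaged genotype, and values as deposited gave 8 for averaged genotype.

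The clock index gave 51 for diet with human APOA1, 5 for genotype on chow, 1 for the interaction and 7 for averaged genotype. Less the 2 libraries highest in neutrophil markers there were 31 for diet without APOA1, 54 with it, 42 for genotype on chow, 243 for the diet effect averaged over genotypes and 8 for averaged genotype, with an agreement r of 0.354 and an r of the genotype effect on Western diet against the diet effect without APOA1 of -0.493. Less the 2 highest in intestine markers there were 8, 99, 1 for genotype on chow, 1 for the interaction, 263 for averaged diet and 3 for averaged genotype. Less Mup and ribosomal protein genes there were 0 for the interaction in limma (563 unadjusted with them) and 6 for averaged genotype. Array weights gave 69, 405, 37 for genotype on chow, 839 for averaged diet and 20 for averaged genotype, with r of 0.457 and -0.502. With an estimated correlation 0 lists were called in each of the 7 comparisons. The cause was not tested for these changes. Median-ratio scaling and the stricter filter kept every count within 1.5-fold.

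Leaving out 1 library gave 8 to 72 genes for diet without APOA1, 6 to 190 with human APOA1, 0 to 0 for genotype on Western diet (limma, 675 unadjusted with all libraries), 2 to 33 for genotype on chow, 1 to 8 for the interaction, 34 to 535 for averaged diet and 2 to 13 for averaged genotype; the report names the libraries. The agreement r was 0.323 to 0.633, and the other r -0.573 to -0.0609. Where 1 DKO/hA1 chow library was left out, the lone one is assumed to vary like the other groups. Lists called numbered 12 to 15, 10 to 14, 13 to 18, 11 to 16, 11 to 19, 9 to 16 and 10 to 17 in the same order, and 10 without DKO Western diet replicate 3 for averaged genotype.

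For named genes, 2499 values under alternatives kept direction and side of the threshold, 763 kept direction only, and 11 changed sign, all for Apoa1 or Apoe effects that were not called. Apoa1 for averaged diet was -0.093 with equal totals, and without 1 library it ranged from -0.043 to 0.20, below 0 without DKO Western diet replicate 3 or DKO/hA1 Western diet replicate 2. Apoe for genotype on Western diet was -0.081 with the code as a random block, and ranged from -0.10 to 0.76 without 1 library, below 0 without DKO Western diet replicate 2 or 3. Apoe for diet without APOA1 ranged from -0.66 to 0.21 without 1 library, above 0 without DKO chow replicate 2 or DKO Western diet replicate 2 or 3, and was 0.21 less the libraries highest in neutrophil markers. Apoe for averaged genotype ranged from -0.70 to 0.078, the latter without DKO/hA1 chow replicate 2. Relative depth ran from 0.514 to 1.31, and the FPKM carry no read numbers, so the precision of low genes is not given.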

Other observations

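The lists of this part were chosen after the data were seen. Intestine transcripts (17 genes) had a mean of 3.34 (log2) in DKO chow replicate 4, 2.16 in DKO/hA1 chow replicate 1 and 1.71 in DKO chow replicate 1, and 0.65 to 1.16 in the others. Neutrophil precursor genes had means of 4.62 in DKO Western diet replicate 2, 4.22 in DKO/hA1 Western diet replicate 3, and 2.35 or less in the others. The clock index was -3.95, -3.94, 1.42 and 0.73 in DKO chow replicates 1 to 4, 0.21 and 0.97 in DKO/hA1 chow, -1.88, -2.35 and -1.31 in DKO Western diet and -3.30, -3.63 and -1.03 in DKO/hA1 Western diet.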
